A study of Mus musculus with 10 samples.

How the data were processed

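The deposited table holds raw UMI counts per gene and nucleus, judged from its name and from its whole numbers, whose totals differ between nuclei. The authors' processing used STAR 2.4.0a24, Seurat and the genome build mm10, per the submitters' processing notes. How UMIs were collapsed, whether intronic reads were counted and how nuclei were chosen for the table is not given in the sources used here. Hippocampus and prefrontal cortex were dissected, frozen and homogenised, and nuclei were isolated in EZ PREP buffer with centrifugation, per the labels' protocols. Libraries follow the DroNc-seq protocol, per the labels' protocols.

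The table has 23589 genes and 13313 columns. Columns were assigned to libraries by the start of their names, which match library titles. A set of 1689 columns carries the library name mHP3, which matches no sample label, and was not used here in any step. Whether these columns belong to a library used here, hippocampus library 3 included, is not known. The remaining 11624 nuclei belong to 10 libraries. The gene positions of 229 of 232 named genes were taken from a GENCODE annotation of the same mouse assembly by symbol.

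The replicate is the unit, a title number within a region, and libraries a and b of number 0 were summed. This gave 4 units per region. Pairs of libraries shared at most 3 barcodes, and the chi-square per degree of freedom was at least 1.34 for every pair of a region. This measure allows for the counting of UMIs and not for the sampling of nuclei, so it does not tell separate mice from repeats. Depth per library ranged from 1443244 to 2600788 UMIs. A self-test on simulated counts, drawn from the real means, library sizes and dispersions with 100 genes changed at each size, gave the precision. In all nuclei, over 12855 genes, it recovered 78% of genes changed by 1 on the log2 scale and 99% of those changed by 2. In excitatory neuron-like nuclei, over 11190 genes, it recovered 76% and 97%. In inhibitory neuron-like nuclei, over 4759 genes, it recovered 41% and 95%. In astrocyte-like nuclei, over 2386 genes, it recovered 52% and 93%, and in endothelial-like nuclei, over 2969 genes, 52% and 98%. For the difference between neuron classes, over 9859 genes, it recovered 37% and 67%. False calls were 2.2% to 7.1% of calls.

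Nuclei were clustered in scanpy 1.11.5 and leidenalg 0.10.2. Counts were scaled to 10000 per nucleus and log-transformed, genes seen in at least 10 nuclei were kept, and 2000 variable genes, 40 principal components and 20 nearest neighbours were used. The Leiden resolution was 2.0. It was set after a first clustering at 1.0 had merged neuronal and glial nuclei and before any regional test, and 1.0 and 4.0 are the halved and doubled alternatives. A cluster was named from marker lists fixed before the data were examined. It needed a mean marker score of at least 0.6, a margin of 0.15 over the next class and 3 supporting markers. A cluster stayed unnamed if it held at least 3 mitochondrial transcripts among its top 10 genes or more markers of another class than of its own. A cluster with few UMIs and none of its own markers among those genes also stayed unnamed. These thresholds were set after the table was read. The names are rebuilt from markers and may differ from those of the study.

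Doublets were scored per library against simulated pairs with 30 neighbours, which called 1381 nuclei, or 11.9%. They stay in the main results and were removed in an alternative. Free RNA was treated by an alternative that removed genes over 3 times higher in all nuclei of a region than in the class.

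Raw UMI counts were summed per unit and class, with at least 20 nuclei per unit. They were tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test, Benjamini-Hochberg) in R 4.3.3. Fold changes are hippocampus minus cortex. CPM values scale the summed counts to the effective library size and are means over units. No batch or replicate block was in the main model. Shares of nuclei and median UMIs were compared by two-sided exact permutation over 70 assignments. Gene lists were fixed before the data were examined and were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and with an estimated one. The difference between neuron classes was an interaction term in 1 model of both classes with the unit as a block. Intervals for few UMIs are exact binomial at 95% and cover counting error only, and a share of 0 was given a limit of 3 counts.

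The genes named were chosen by a rule fixed before the data were examined. They passed an adjusted p under 0.05, averaged at least 20 CPM and had every unit of one region above every unit of the other. The largest folds were taken, 10 per direction for all and for excitatory nuclei, 6 for inhibitory and astrocyte-like nuclei and 3 for the endothelial-like class and the interaction. Up to 4 members of each list with the smallest p were added, with the sex-linked genes. Predicted genes and those with a Rik name were counted and not named. Some genes that this rule names are not reported here. Genes with overlapping or near-identical copies, such as ribosomal protein genes with pseudogenes and Tsix, which is antisense to Xist, can share reads and are uncertain.

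Alternatives were a replicate block, DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, each library as its own unit, each unit left out, other cluster resolutions, doublets and free RNA removed, at least 400 detected genes per nucleus, and limma on logit shares. Those added after seeing the data were numbers 1 to 3 alone, number 0 alone, number 0 as a model term, unnamed clusters removed, doublets removed in all nuclei, a UMI floor, and clusters 14 and 16 counted as glia. Lists of thalamic, midbrain and telencephalic genes were also written after the clusters were seen. In excitatory nuclei the same-numbered units of the 2 regions deviated together, with correlations of 0.552, 0.185, 0.199 and 0.212 for numbers 0 to 3, so the numbers formally pair the units there. With numbers 1 to 3 alone the values were 0.01, -0.004 and -0.022, so number 0 carried that correlation and the block stayed an alternative. The comparison with other splits was limited in this class to the 8 splits that part the units of every number. In all nuclei the values were 0.503, 0.159, 0.063 and 0.111 for numbers 0 to 3, and -0.012, -0.153 and -0.115 with numbers 1 to 3 alone. In endothelial-like nuclei they were 0.435, 0.126, 0.102 and 0.071, and 0.062, 0.027 and 0.049 with numbers 1 to 3 alone, where each unit correlated best with its own number. In neither did every value exceed 0.1, the bound for pairing, so all 35 splits were used there.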

Results

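Single-nucleus RNA was measured by DroNc-seq, in which nuclei and barcoded beads are enclosed together in droplets, in archived frozen brain tissue of C57BL/6 mice. There were 10 libraries, 5 of hippocampus and 5 of cortex. The cortex was dissected as prefrontal cortex, per the labels' protocols. The series design names 4 mice and 2 regions. The library titles carry the numbers 0 to 3, and number 0 has a library a and a library b in each region. The libraries sharing a number and a region were summed, which gave 4 units per region. The labels do not tie a title number to a mouse. P-values therefore measure the spread between these units, which may be technical. Libraries 1 to 3 of a region differed from each other by a chi-square per degree of freedom of 1.34 to 1.40 in cortex and 1.5 to 1.71 in hippocampus. Libraries 0a and 0b, which share a number, differed by 1.80 in cortex and 1.43 in hippocampus. Number 0 stood apart from numbers 1 to 3 in both regions, with values of 4.05 to 6.85, so counts of genes are also given with numbers 1 to 3 and, where it was run, with number 0 alone. Number 0 alone takes libraries a and b as 2 replicates of what is 1 unit per region, so its counts rest on the spread between repeat libraries only.

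The table held 23589 genes and the 10 libraries held 11624 nuclei, 5658 of hippocampus and 5966 of cortex. In hippocampus the total was 1972542 UMIs in library 0a, 1861644 in 0b, 1593057 in 1, 1443244 in 2 and 1794663 in 3. In cortex it was 2600788 in library 0a, 1807068 in 0b, 2375881 in 1, 2384141 in 2 and 2396008 in 3. The median nucleus held 1026 ± 166 UMIs in hippocampus and 1515 ± 665 in cortex (SD, n = 4 units each), a difference of -489.2 with a two-sided exact permutation p of 0.114. Cortex unit 0 set most of that difference, which was -159.4 without it and -81.5 with numbers 1 to 3. The nucleus with the fewest UMIs held 278 ± 12.9 in hippocampus and 520 ± 96.1 in cortex (SD, n = 4), with a two-sided exact permutation p of 0.0286. Mitochondrially encoded transcripts were 0.111% to 0.136% of UMIs in the hippocampal libraries and 0.044% to 0.052% in the cortical ones.

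The first comparison asked which kinds of nuclei each region held. Astrocyte-like nuclei were 11.8% ± 2.97 of hippocampal and 2.77% ± 1.99 of cortical nuclei (SD, n = 4 units each). Oligodendrocyte-like nuclei were 5.73% ± 0.835 in hippocampus and 0.341% ± 0.6 in cortex. Excitatory neuron-like nuclei were 44.7% ± 9.21 in hippocampus and 72.2% ± 5.10 in cortex. Inhibitory neuron-like nuclei were 3.06% ± 0.993 in hippocampus and 9.68% ± 0.163 in cortex. Ependymal-like nuclei, whose class is led by genes of motile cilia, were 1.03% ± 0.596 in hippocampus, while cortex held 0 of 5966, which allows a share of up to 0.0503% by counting error alone.

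Each of these 5 classes separated the regions completely, every unit of one region lying above every unit of the other. Each reached a two-sided exact permutation p of 0.0286, the smallest that 4 against 4 units can give. After Benjamini-Hochberg adjustment over the 10 classes each p was 0.0571, so no class passed. With 5 of 10 classes at the smallest p, 0.0571 is the lowest value this adjustment can give. The failure to pass therefore says nothing about the size of the differences. In an alternative, limma on logit shares with a replicate block, which is no exact permutation test, the Benjamini-Hochberg adjusted p of these 5 classes was 0.000661 to 0.0105. With clusters 14 and 16 counted as glia the astrocyte-like difference was 5.58 points with an exact permutation p of 0.0571, and with doublet calls removed the ependymal-like share had an exact permutation p of 0.143. Oligodendrocyte precursor-like nuclei were 1.87% ± 0.324 in hippocampus and 1.15% ± 0.492 in cortex, with an adjusted exact permutation p of 0.122. Meningeal fibroblast-like nuclei were 0.925% ± 0.292 and 1.65% ± 0.394, with the same adjusted exact permutation p of 0.122. Microglia-like nuclei were 1.68% ± 0.279 and 1.87% ± 0.801, and endothelial-like nuclei 3.05% ± 0.701 and 3.21% ± 1.49, each with an adjusted exact permutation p of 0.984. The 24 choroid plexus-like nuclei all came from hippocampus unit 0.

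**Figure D1:**
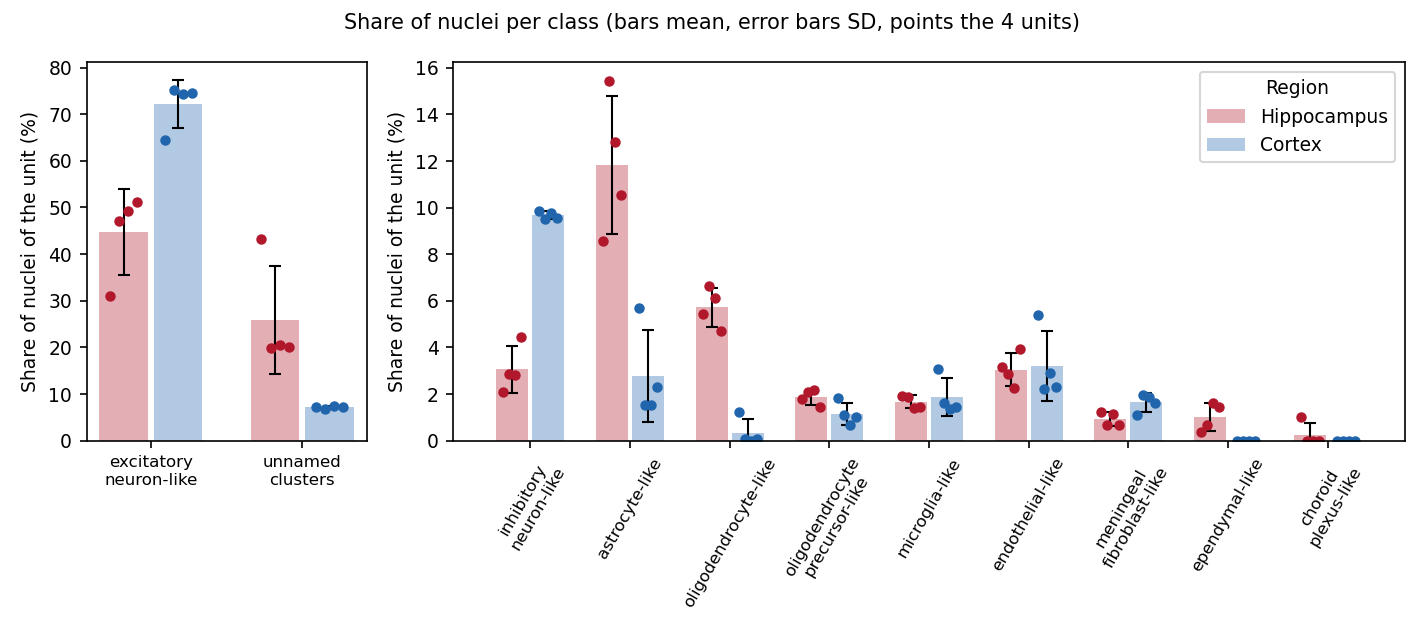
Share of nuclei per class as a percentage of the nuclei of the unit, with bars for the mean, error bars for the SD and points for the 4 units of hippocampus and of cortex. Astrocyte-like nuclei were 11.8% of hippocampal and 2.77% of cortical nuclei, and unnamed clusters held 25.9% of hippocampal nuclei.

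Clusters that could not be named held 25.9% ± 11.6 of hippocampal and 7.18% ± 0.300 of cortical nuclei (SD, n = 4), and this gap can move every share above. Cluster 2, led by mitochondrial rRNAs with a median of 448 UMIs, held 33.3% of hippocampus unit 0 and at most 1.79% of each other unit. Cluster 16, led by astrocyte genes, had marker scores of 0.669 for excitatory neuron and 0.611 for astrocyte. It held 4.24% of cortical and 0.757% of hippocampal nuclei. Cluster 14, led by myelin genes with excitatory markers, held 2.32% of cortical and 3.95% of hippocampal nuclei. The hippocampal libraries also reached lower UMI totals. With only nuclei of at least 646 UMIs, a floor chosen after seeing the data, the astrocyte-like difference was 8.55 points against 9.07 and the oligodendrocyte-like difference 3.11 against 5.38. With numbers 1 to 3 these differences were 11.14 and 5.78 points. At 3 against 3 units no class can pass, and number 0 alone is 1 unit per region.

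Within the excitatory neuron-like nuclei the regions held different clusters. Dentate granule-like nuclei, led by C1ql2, Prox1 and Dsp, were 52.7% ± 7.97 of those of hippocampus and 0.10% of those of cortex (SD, n = 4). CA1 pyramidal-like nuclei were 19.3% ± 7.78 and CA3 pyramidal-like nuclei 8.34% ± 1.04 of the hippocampal ones. In cortex, layer 2-4-like nuclei were 48.8% ± 4.02, layer 6-like nuclei 17.8% ± 3.41 and layer 5-like nuclei 8.01% ± 1.60. Layer 2-4-like nuclei were also 23.7% of the excitatory nuclei of hippocampus unit 0, against 2.82% to 3.44% in the other hippocampal units. Excitatory nuclei with no named subtype were 25.1% in cortex and 5.20% in hippocampus. These shares were set by the genes that define the clusters and were not tested.

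**Figure D2:**
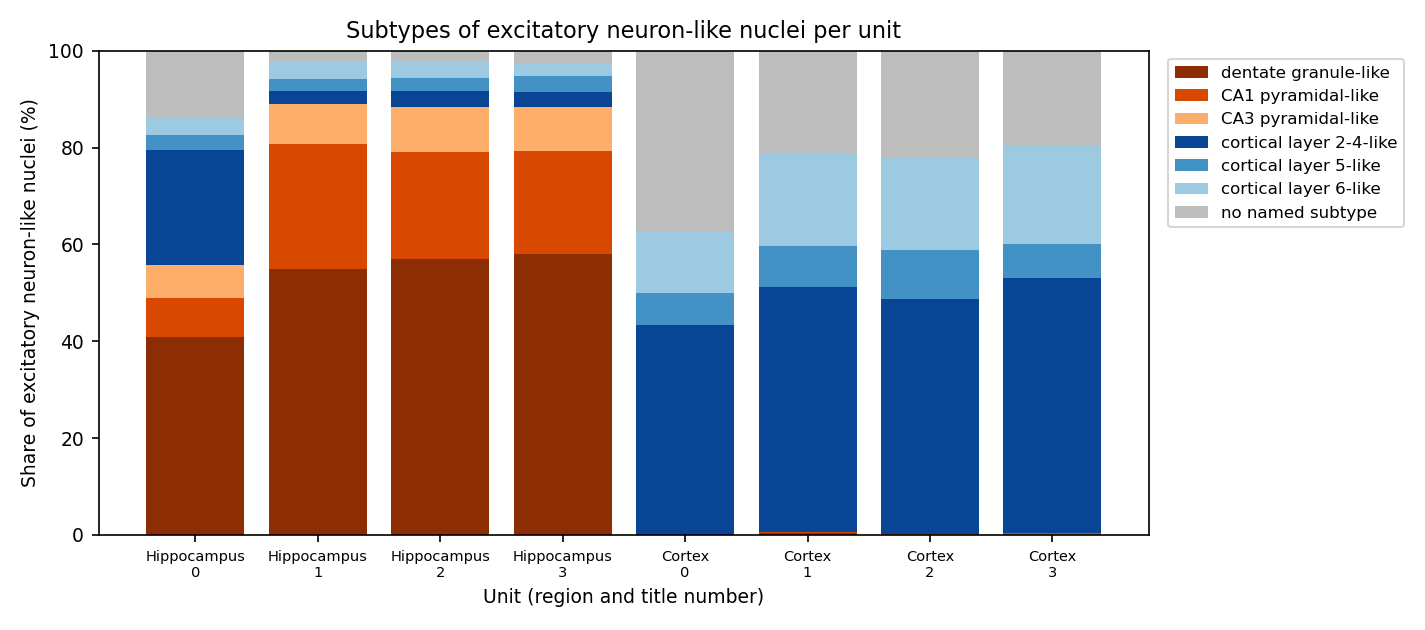
Stacked shares of the excitatory neuron-like nuclei of each of the 8 units by subtype, as a percentage of those nuclei. Dentate granule-like nuclei were 40.9% to 58.0% in the hippocampal units, and layer 2-4-like nuclei 43.3% to 52.7% in the cortical units.

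The next comparison took the summed RNA of all nuclei of a unit and asked which genes differed between the regions. C1ql2, a secreted synaptic protein of the C1q family, averaged 68.1 CPM in hippocampus and 0.40 CPM in cortex, a log2 fold change of 7.40 ± 0.37 (SE, n = 4 units each). Prox1, a transcription factor of dentate granule cells, rose by 3.51 ± 0.13, and Zbtb20, a zinc-finger transcription factor, by 3.12 ± 0.19. Agt, which encodes angiotensinogen, rose by 4.41 ± 0.35, from 2.5 to 50.1 CPM. In the other direction Abi3bp, an extracellular matrix protein gene, had a log2 fold change of -2.71 ± 0.34 and the cholecystokinin receptor gene Cckbr -2.27 ± 0.31. Of 12855 genes tested, 1181 were higher in hippocampus and 1097 higher in cortex at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

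Other genes with the largest rises in hippocampus were Slc17a6, a vesicular glutamate transporter gene (3.46 ± 0.22), Prkcd, a protein kinase C gene (3.82 ± 0.53), St18 (3.69 ± 0.27), Ttn (3.53 ± 0.35), Mndal (3.53 ± 0.28) and Shisa6, an AMPA receptor auxiliary subunit gene (3.19 ± 0.33). Slc17a6 led the unnamed clusters 9 and 22 of the hippocampal libraries, and Prkcd reached 1598 CPM in cluster 22. Lower in hippocampus were Adam33 (-2.17 ± 0.45), Coch (-2.10 ± 0.40), Col6a1 (-2.08 ± 0.24), Hkdc1 (-2.01 ± 0.41), the immediate early gene Egr4 (-1.89 ± 0.33), the syntaxin gene Stx1a (-1.86 ± 0.34) and Herc6 (-1.85 ± 0.29). Hippocampus unit 0 lay far above the other hippocampal units for Adam33 (31.5 CPM, others 2.5 to 7.0) and Stx1a (141.5, others 38.7 to 42.1). The same held for Col6a1 (56.3, others 21.7 to 25.8) and Abi3bp (15.1, others 2.8 to 4.5). Adjusted p over the genes with the largest folds ran from 1.03e-08 for Prox1 to 0.005 for Adam33 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In mm10 coordinates Prox1 lies on chromosome 1 from 190118035 to 190170714, C1ql2 on chromosome 1 from 120340582 to 120343174, Zbtb20 on chromosome 16 from 42875881 to 43642602 and Agt on chromosome 8 from 124556534 to 124569706. All of these are protein-coding genes.

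Of the hippocampal neuron genes, 15 of 22 rose in hippocampus and 2 fell (16 and 2 adjusted over the list alone). The list passed camera, a competitive gene set test, with a Benjamini-Hochberg adjusted p of 9.2e-29, and it held with adjusted p = 0.0106 with an estimated correlation. Dsp, which encodes desmoplakin, had 233 UMIs in hippocampus and 1 in cortex, a ratio of 311 with a 95% counting interval of 55.3 to 12334. Coch, a list member known from CA3, fell. Of the neocortical neuron genes, 12 of 20 fell and 1 rose (14 and 2 adjusted over the list alone). Lmo4 (-1.16 ± 0.12), Otof (-1.74 ± 0.20), Tbr1 (-1.60 ± 0.22) and Fezf2 (-1.05 ± 0.16) were among those that fell. That list also held, with camera's adjusted p = 0.0106 with an estimated correlation. With numbers 1 to 3 both lists held, at an adjusted p of 0.00872, while with a replicate block the hippocampal list held (0.028) and the neocortical list did not (0.17).

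Myelin genes rose in hippocampus in 15 of 17 cases and fell in 0 (16 and 0 adjusted over the list alone). Mag rose by 1.83 ± 0.13, the aspartoacylase gene Aspa by 2.01 ± 0.14 and the connexin gene Gjc3 by 1.99 ± 0.17. The list passed with camera's adjusted p = 0.0106 with an estimated correlation, but had 0.0573 with numbers 1 to 3. Astrocyte transport and channel genes rose in 11 of 15 cases (14 adjusted over the list alone), with Gja1, the connexin 43 gene, at 1.68 ± 0.19 and the glutamate transporter gene Slc1a3 at 1.24 ± 0.17. Their call was lost, with camera's adjusted p = 0.0962 with an estimated correlation. The summed RNA of all nuclei also reflects the shares of oligodendrocyte-like and astrocyte-like nuclei, which were 5.73% and 11.8% in hippocampus against 0.341% and 2.77% in cortex.

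Immediate early genes, which neuronal activity induces, fell in hippocampus in 11 of 17 cases and rose in 0 (13 and 0 adjusted over the list alone). Arc had a log2 fold change of -1.20 ± 0.13, Nr4a1 of -1.14 ± 0.16 and Npas4 of -1.23 ± 0.18. The call was lost, with camera's adjusted p = 0.113 with an estimated correlation, but it held with numbers 1 to 3 at 0.0338. Cortex unit 0 lay far from the others for Egr4, with 24.6 CPM against at least 64.2 CPM. All 8 tested mitochondrially encoded transcripts rose, with mt-Rnr2 at 1.42 ± 0.10, and camera's adjusted p was 0.0383 with an estimated correlation, or 0.182 with numbers 1 to 3 and 0.17 with a replicate block. Cytosolic ribosomal protein genes rose in 22 of 30 cases (25 adjusted over the list alone), with Rpl3 at 1.03 ± 0.14, and the call was lost at camera's adjusted p = 0.0785 with an estimated correlation. Cluster 2, led by mitochondrial transcripts, held 33.3% of the nuclei of hippocampus unit 0 and at most 1.79% of hippocampus units 1 to 3. Mitochondrial transcripts were 0.113% and 0.134% of UMIs in hippocampus libraries 0a and 0b and 0.111% to 0.136% in libraries 1 to 3. The higher mitochondrial share was thus not confined to unit 0.

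Axon guidance genes rose in 15 of 28 cases and fell in 7 (16 and 7 adjusted over the list alone). The netrin relative Ntng1 rose by 2.39 ± 0.16, Sema5a by 2.4 ± 0.21, Slit1 by 1.69 ± 0.19 and the ephrin receptor gene Epha7 by 1.23 ± 0.15. Ntng1 was among the genes that led the unnamed cluster 22, which held 171 nuclei of hippocampus and 0 of cortex. Sema5a was among those that led the dentate granule-like cluster. The call of the axon guidance list was lost, with camera's adjusted p = 0.0562 with an estimated correlation, but it held with numbers 1 to 3 at 0.0338. Of the striatal medium spiny neuron genes 3 of 11 fell, among them Meis2 (-1.55 ± 0.18) and Foxp1 (-0.50 ± 0.13), and camera's adjusted p was 0.106 with an estimated correlation. Foxp1 and Meis2 are also expressed by cortical neurons. Corticosteroid genes did not pass as a list, but the mineralocorticoid receptor gene Nr3c2 rose by 1.47 ± 0.16 and Fkbp5 by 0.85 ± 0.18.

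**Figure D3:**
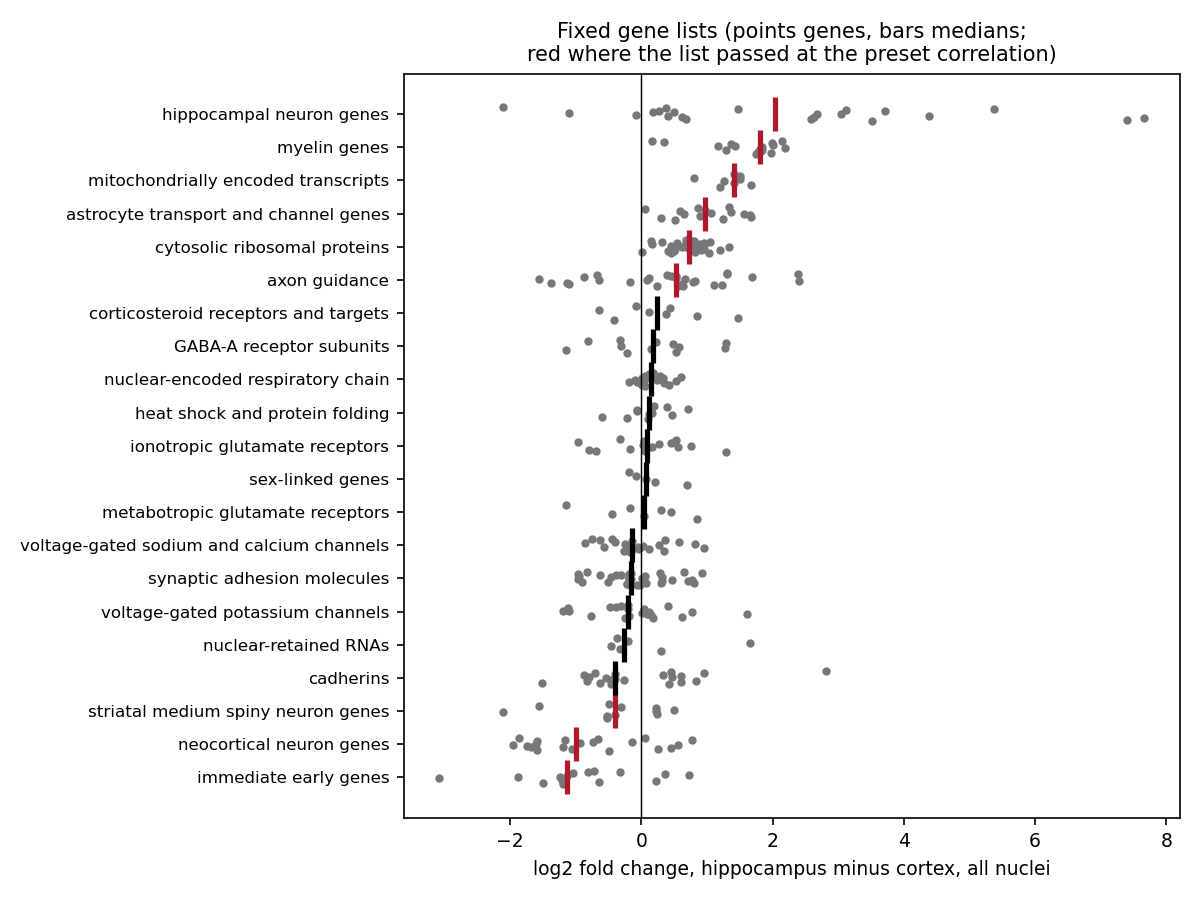
Log2 fold change, hippocampus minus cortex, in all nuclei for the members of the 21 fixed gene lists, with points for genes and bars for list medians, drawn red where a list passed at the preset correlation. The 9 red lists include the hippocampal neuron, myelin and neocortical neuron genes, and the fitted value of Dsp rests on 1 cortical UMI. Fewer lists passed with an estimated correlation.

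Lists of receptors and channels held genes that moved both ways. Of 17 ionotropic glutamate receptor genes 2 rose and 3 fell (5 and 3 adjusted over the list alone), Gria1 by 1.29 ± 0.14 upward and Gria3 with -0.69 ± 0.07, while 9 rose and 3 fell with numbers 1 to 3 and 5 rose and 3 fell with a replicate block. Of 12 GABA-A receptor subunit genes 5 rose and 2 fell, with Gabra5 at 1.27 ± 0.24 and Gabra3 at -1.15 ± 0.16. Of 22 potassium channel genes 4 rose and 6 fell, with Kcnh7 at -1.13 ± 0.14. Sodium and calcium channel genes gave 4 and 5 of 22, synaptic adhesion genes 5 and 8 of 33, cadherins 4 and 4 of 21 and metabotropic glutamate receptor genes 1 and 1 of 7. Pcdh20, a protocadherin gene, rose by 2.82 ± 0.28, while Grm8 fell by 1.15 on the log2 scale. Of the nuclear-retained RNAs 2 of 6 rose and 3 fell, with Neat1 at 1.65 ± 0.12 and Snhg11 at -0.46 ± 0.08. Of the nuclear-encoded respiratory chain genes 2 of 20 rose, Uqcrb by 0.53 ± 0.12 and Cox7c by 0.60 ± 0.16. No heat shock gene of 11 passed in all units, while 3 rose and 1 fell with a replicate block and 2 rose and 3 fell with numbers 1 to 3. None of these lists passed camera.

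No sex-linked gene passed the test between the regions in all units. Ddx3y, on the Y chromosome, averaged 158 CPM in hippocampus and 136 CPM in cortex, a log2 fold change of 0.22 ± 0.10 with an adjusted p of 0.159 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With numbers 1 to 3 Ddx3y in all nuclei rose by 0.26, with an adjusted p of 0.0174 in edgeR with Benjamini-Hochberg adjustment, and with number 0 alone Tsix in all nuclei rose by 1.84, with 0.0178. Of 4 sex-linked genes tested in excitatory neuron-like nuclei with numbers 1 to 3, Kdm5d fell. For all nuclei, numbers 1 to 3 alone gave 4128 genes, number 0 as a term of the model gave 3665, and number 0 alone, with libraries a and b of 1 unit per region as replicates, gave 2344, against 2278 in all units. The count ran from 1570 without hippocampus unit 1 to 3094 without cortex unit 0.

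Excitatory neuron-like nuclei were compared next, to ask which genes differed within this class. Prox1 averaged 180 ± 23.2 CPM in hippocampus and 4.60 CPM in cortex, a log2 fold change of 5.34 ± 0.26 (SE, n = 4 units each). Zbtb20 rose by 4.88 ± 0.18, from 104 to 3047 CPM. The AMPA receptor subunit gene Gria1 rose by 1.83 ± 0.13, from 507 to 1806 CPM. In cortex the layer genes Cux2 (-2.22 ± 0.55) and Rorb (-1.95 ± 0.54) were higher. Of 11190 genes, 981 were higher in hippocampus and 848 higher in cortex at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Dentate granule, CA1 and CA3-like clusters made up most of the class in hippocampus, and layer 2-4, 5 and 6-like clusters most of it in cortex.

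C1ql2 had 403 UMIs in hippocampus and 1 in cortex, a ratio of 746 with a 95% counting interval of 133 to 29554. Dsp had 182 and 1 UMIs, a ratio of 337 with an interval of 59.7 to 13386. St18 (5.91 ± 0.43), Mndal (5.37 ± 0.36), Ttn (4.76 ± 0.42), Shisa6 (4.28 ± 0.34) and Prkcd (4.12 ± 0.36) also rose. The genes that were lower in hippocampus included Abi3bp (-2.46 ± 0.44), Herc6 (-2.23 ± 0.38), Coch (-2.13 ± 0.55), the cerebellin gene Cbln2 (-2.10 ± 0.36), the guanylate cyclase gene Gucy1a3 (-2.09 ± 0.25), Dpp10 (-2.04 ± 0.49), the autotaxin gene Enpp2 (-1.94 ± 0.39) and the histamine receptor gene Hrh3 (-1.94 ± 0.28). Hippocampus unit 0 lay far above the other hippocampal units in 8 of the 10 genes that fell, for example with 93.6 CPM of Cux2 against at most 6.80.

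**Figure D4:**
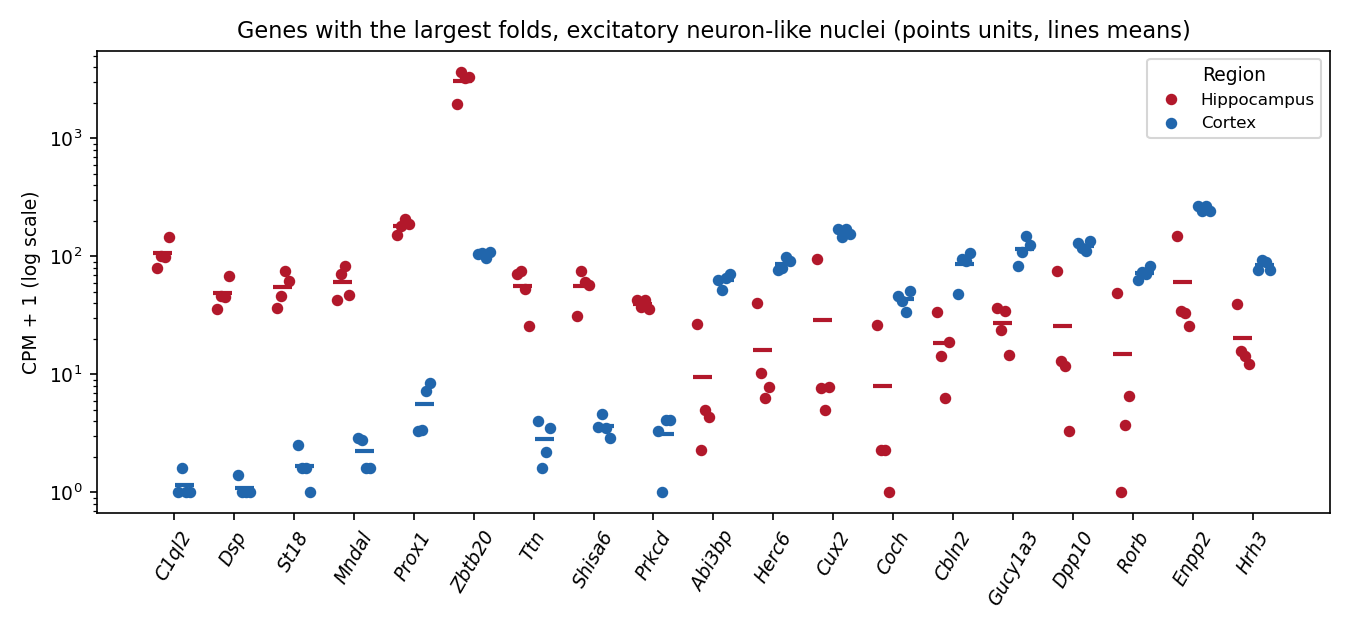
CPM plus 1 on a log scale in excitatory neuron-like nuclei for genes with the largest folds in each direction, with points for the 4 units of each region and lines for their means. Zbtb20 averaged 3047 CPM in hippocampus and 104 CPM in cortex, and hippocampus unit 0 lay above the other hippocampal units for Cux2 and Rorb.

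Of the hippocampal neuron genes 17 of 22 rose and 2 fell in this class (17 and 2 adjusted over the list alone), with camera's adjusted p = 0.00991 with an estimated correlation and 0.0174 with numbers 1 to 3. Axon guidance genes rose in 16 of 28 cases and fell in 4 (17 and 7 adjusted over the list alone), with camera's adjusted p = 0.0347 with an estimated correlation, 0.0204 with numbers 1 to 3 and 0.14 with a replicate block. Sema5a rose by 3.47 ± 0.22, the neuropilin gene Nrp1 by 2.19 ± 0.19, Slit1 by 2.19 ± 0.19 and Epha7 by 1.74 ± 0.15. Neocortical neuron genes fell in 13 of 20 cases and rose in 2 (15 and 3 adjusted over the list alone), and camera's adjusted p was 0.0597 with an estimated correlation, or 0.036 with numbers 1 to 3. Mef2c (-1.46 ± 0.23), Tbr1 (-1.24 ± 0.21) and Lmo4 (-0.83 ± 0.12) fell, while Lmo3 rose by 1.20 ± 0.22. The preset correlation also called the immediate early genes, of which 10 of 17 fell and 3 rose, and the estimated one did not, with camera's adjusted p of 0.346. Egr1 (-1.23 ± 0.17), Nr4a1 (-0.90 ± 0.16) and Arc (-0.77 ± 0.13) were among those that fell, and Egr2 had 0.90 CPM in hippocampus and 11.2 CPM in cortex. A cortical layer 2-4-like cluster of 220 nuclei was led by Fosb, Npas4 and Fos.

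Ribosomal protein genes rose in 20 of 29 cases (23 adjusted over the list alone), with Rpl3 at 1.32 ± 0.18 and camera's adjusted p of 0.179 with an estimated correlation. Mitochondrially encoded transcripts rose in 5 of 8 cases, with mt-Rnr2 at 1.52 ± 0.20 and camera's adjusted p of 0.0545 with an estimated correlation. Myelin genes rose in 5 of 12 cases, with Mbp at 1.35 ± 0.19 and camera's adjusted p of 0.0983 with an estimated correlation. Oligodendrocyte-like nuclei were 5.73% of hippocampal and 0.341% of cortical nuclei, so free RNA or doublets could raise myelin genes here. The myelin list was not tested with either removed. With genes open to free RNA removed, 82 of the 89 named genes called in this class kept their call and 1 lost it. The rest were not tested there. Striatal genes fell in 4 of 8 cases, Meis2 with -1.82 ± 0.33, and camera's adjusted p was 0.170 with an estimated correlation. Among receptors, Gabra5 rose by 1.72 ± 0.24, Gabra2 by 0.92 ± 0.13 and Grm5 by 0.62 ± 0.14, while Gabra3 (-1.51 ± 0.24) and Grm3 (-1.25 ± 0.27) fell. Of 21 potassium channel genes 4 rose and 4 fell, with Kcnd2 at 1.20 ± 0.23 and Kcnh7 at -0.94 ± 0.15. Of 22 sodium and calcium channel genes 5 rose, Scn3b by 1.43 ± 0.13 and Cacna1h by 1.24 ± 0.13 among them, and none fell (5 and 1 adjusted over the list alone), while with a replicate block 5 rose and 7 fell. Nr3c2 rose by 2.11 ± 0.19 and Fkbp5 by 1.36 ± 0.21, while the glucocorticoid receptor gene Nr3c1 fell by 0.61 on the log2 scale. Numbers 1 to 3 alone gave 3586 genes, number 0 as a term gave 3102 and number 0 alone, again from repeat libraries of 1 unit per region, gave 1158, against 1829 in all units. The count ran from 1136 without hippocampus unit 1 to 2626 without hippocampus unit 0.

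Inhibitory neuron-like nuclei, 162 of hippocampus and 577 of cortex in clusters 8 and 17, showed few differences. Gria1 rose by 1.21 ± 0.16 in hippocampus, from 862 to 2031 CPM, and Zbtb20 by 1.17 ± 0.22 (SE, n = 4 units each). The Golgi protein gene Golm1 rose by 2.11 ± 0.48 and the collagen gene Col25a1 by 1.33 ± 0.28. Lower in hippocampus were the calcium pump gene Atp2b4 (-2.0 ± 0.44), Lmo4 (-1.53 ± 0.28), Arpp21 (-1.12 ± 0.25) and Camk2n1 (-0.92 ± 0.21). Arpp21 is among the excitatory neuron markers, and Slc17a7, another of them, had 99.9 CPM in cluster 8 and 138.1 CPM in cluster 17, against 239.4 to 465.8 CPM in the excitatory clusters. Of 4759 genes, 5 were higher in each region at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Axon guidance genes passed camera with adjusted p = 0.0323 with an estimated correlation, although 0 of 12 members passed over all genes and 5 rose adjusted over the list alone. With numbers 1 to 3 that adjusted p was 0.142 and with a replicate block 0.259.

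The preset correlation also called the neocortical, immediate early, corticosteroid and striatal lists in inhibitory nuclei, all downward, and each had camera's adjusted p of 0.155 with an estimated correlation. The numbers 1 to 3 gave 123 genes in edgeR (48 higher in hippocampus, 75 in cortex), number 0 alone 0 (242 at an unadjusted p under 0.05) and number 0 as a term 82 (37 and 45), against 10 in all units (5 and 5). The replicate block gave 64 (23 and 41) and no filter on low counts 50 (8 and 42). The count ran from 1 without hippocampus unit 3 to 76 without hippocampus unit 0. In all units there were 383 genes at an unadjusted p under 0.05.

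A test of the difference between the classes asked whether the regional effect was the same in both kinds of neuron. In 9859 genes, the log2 fold change, hippocampus minus cortex, was higher in inhibitory than in excitatory nuclei for 132 and lower for 201 at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Prox1 differed by -4.69 ± 0.51 (SE, n = 4 units per region), Slc26a10 by -4.58 ± 1.37 and Dock11 by -4.15 ± 0.68. The transcription factor gene Maf differed by 2.32 ± 0.41, Col26a1 by 2.93 ± 0.55 and Gpc6 by 2.45 ± 0.65. These are differences of signed values, since Maf had -1.58 in excitatory and 0.91 in inhibitory nuclei. In excitatory nuclei Col26a1 had -2.08, Gpc6 -1.36, Prox1 5.34, Slc26a10 3.83 and Dock11 3.57. Of the genes named for this test, only Maf was tested in inhibitory nuclei alone. The excitatory nuclei differed in subtype between the regions, dentate granule-like nuclei being 52.7% of them in hippocampus and 0.1% in cortex. Prox1 and Slc26a10 led the dentate granule-like cluster. The test therefore cannot tell subtype make-up from regulation within a kind of neuron. Numbers 1 to 3 alone gave 361 genes. The count ran from 195 without hippocampus unit 3 to 433 without hippocampus unit 0.

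Astrocyte-like nuclei, 625 of hippocampus and 161 of cortex in cluster 4, differed in 88 genes. The unnamed cluster 16, also led by astrocyte genes, held 250 nuclei of cortex and 45 of hippocampus and is not in this comparison. No gene comparison was run with it added, so the cortical side holds only part of the nuclei led by astrocyte genes. Agt rose by 3.96 ± 0.37 in hippocampus, from 40.4 to 774 CPM (SE, n = 4 units each). Hsd11b1, whose enzyme regenerates active glucocorticoid, had 142 UMIs in hippocampus and 2 in cortex, a ratio of 31.2 with a 95% counting interval of 8.50 to 261. The matricellular gene Sparc rose by 2.4 ± 0.31, Timp4 by 2.33 ± 0.47, the cystatin C gene Cst3 by 1.78 ± 0.23 and Tmem229a by 1.52 ± 0.37. In the other direction the prostaglandin D synthase gene Ptgds had -2.42 ± 0.26, with 467 CPM in hippocampus and 2658 CPM in cortex. Of 2386 genes, 40 were higher in hippocampus and 48 higher in cortex at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

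At the doubled cluster resolution this class held clusters 7, 29 and 30, and cluster 30, led by Agt, Itih3 and Slc6a11, held 134 nuclei of hippocampus and 2 of cortex. Cluster 29, led by Gfap, Myoc and Aqp4, held 90 of hippocampus and 63 of cortex, and cluster 7 held 395 and 95. The make-up of the class thus differed between the regions. Agt and Gja1 are among the genes that led cluster 4, and Ptgds led the meningeal fibroblast-like cluster. Lamp5 (-3.41 ± 0.57), Rgs4 (-2.68 ± 0.43), Mef2c (-2.02 ± 0.32), Slc4a10 (-1.63 ± 0.36) and Meis2 (-1.57 ± 0.35), which neurons express, were also lower in hippocampus. Of the neocortical neuron genes 3 of 4 fell, Lamp5, Mef2c and Lmo4 (-1.28 ± 0.30), and the list passed with camera's adjusted p = 0.0274 with an estimated correlation, but had 0.172 with numbers 1 to 3 and 0.136 with a replicate block. Of the astrocyte transport and channel genes 4 of 13 rose (6 rose and 1 fell adjusted over the list alone). These included Atp1b2 (1.15 ± 0.22), Gja1 (1.08 ± 0.22) and Slc1a3 (0.75 ± 0.22), and camera's adjusted p was 0.118 with an estimated correlation. The sodium and calcium channel, myelin, mitochondrial and ribosomal lists had the same camera adjusted p of 0.118 with an estimated correlation.

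**Figure D5:**
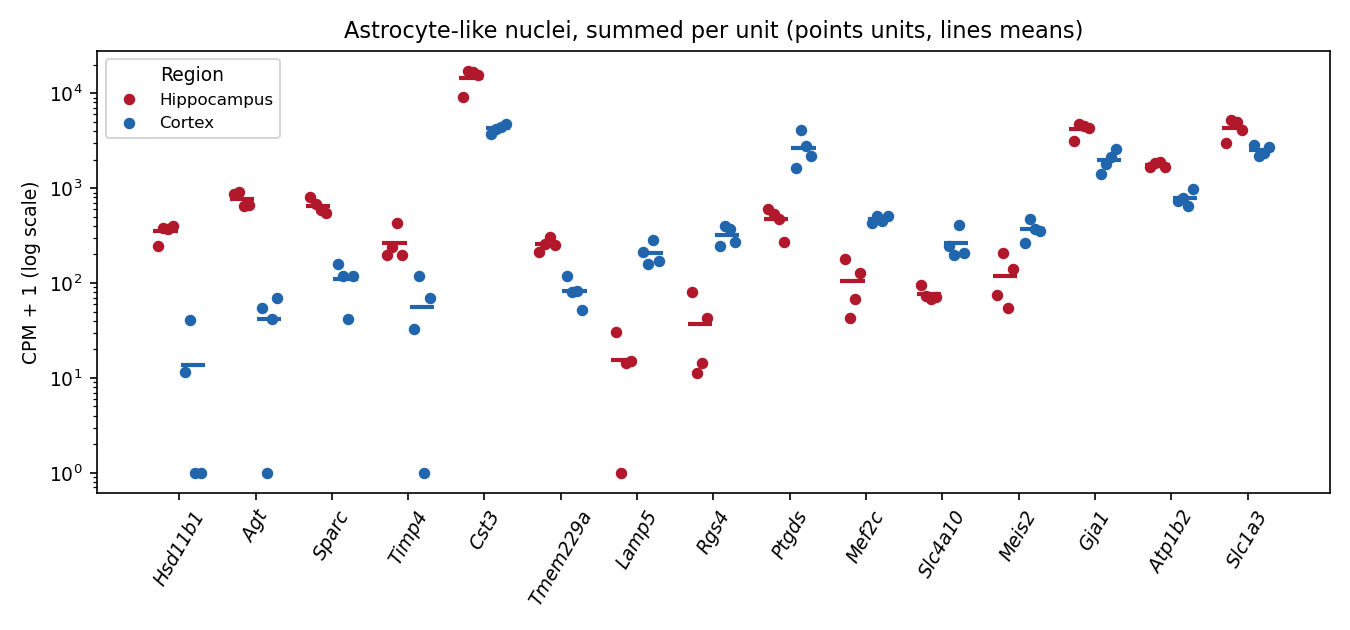
CPM plus 1 on a log scale in astrocyte-like nuclei for the genes with the largest folds and 3 transport genes, with points for the 4 units of each region and lines for their means. Agt averaged 774 CPM in hippocampus and 40.4 CPM in cortex, and Ptgds 467 and 2658 CPM.

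In astrocyte-like nuclei numbers 1 to 3 alone gave 282 genes, number 0 as a term 134 and number 0 alone 32, against 88 in all units. The count ran from 47 without hippocampus unit 1 to 183 without cortex unit 0, and with doublet calls removed 69 genes passed. In that setting 6 of the 25 named calls were lost, and Lamp5, Slc4a10 and Nrxn3 fell under the filter on low counts and were not tested. In mm10 coordinates Hsd11b1 lies on chromosome 1 from 193221634 to 193264075 and is protein-coding.

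Endothelial-like nuclei, 175 of hippocampus and 187 of cortex in cluster 13, which Rgs5 of pericytes also led, differed in 95 genes. Arpp21 (-2.31 ± 0.37), Gria3 (-2.23 ± 0.39) and Nrcam (-2.04 ± 0.45), all expressed by neurons, were lower in hippocampus (SE, n = 4 units each). The histone gene H3f3a rose by 1.76 ± 0.41, Rpl34 by 1.44 ± 0.29 and mt-Co1 by 1.42 ± 0.27. Of 2969 genes, 33 were higher in hippocampus and 62 higher in cortex at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ribosomal protein genes rose in 5 of 20 cases (19 adjusted over the list alone), Rpl37 by 1.98 ± 0.40. Mitochondrially encoded transcripts rose in 5 of 8, synaptic adhesion genes fell in 3 of 7, and nuclear-retained RNAs fell in 3 of 6 (4 adjusted over the list alone), with Miat at -1.79 ± 0.39. For the nuclear-retained RNAs camera's adjusted p was 8.4e-05 at the preset correlation and 0.183 with an estimated one.

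No list held in endothelial-like nuclei in all units, the smallest camera adjusted p being 0.126 with an estimated correlation. With numbers 1 to 3 the mitochondrial and immediate early lists had 0.037 and the ribosomal list 0.0434. With doublet calls removed 3 genes passed, none of them a gene named here, and with DESeq2 52 (25 higher in hippocampus, 27 in cortex). Arpp21, Gria3 and Nrcam fell under the filter on low counts without the doublet calls and were not tested there. Numbers 1 to 3 alone gave 119 genes (61 higher in hippocampus, 58 in cortex), number 0 alone 188 (55 and 133) and the replicate block 162 (69 and 93), against 95 (33 and 62). The count ran from 10 without hippocampus unit 3 to 168 without hippocampus unit 0.

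Oligodendrocyte-like, oligodendrocyte precursor-like and microglia-like nuclei were not compared by gene. In 1 region or the other, fewer than 3 units held at least 20 such nuclei. These were 4 units of hippocampus and 0 of cortex for oligodendrocyte-like nuclei, 3 and 1 for precursors, and 2 and 3 for microglia-like nuclei. The comparison of astrocyte with oligodendrocyte effects needs those nuclei and was not made.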

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

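The tests of the UMI floor and the mixed clusters for the shares of glia, the test of doublets, the limit to 8 splits for excitatory neuron-like nuclei and the test of diluted astrocyte RNA were chosen only after the result was seen, as were the alternatives with numbers 1 to 3 or number 0 alone. The test of doublets and its bounds were set after its counts were seen and replaced tests on Slc17a6 alone, which gave 0.70 and 1.42 times the highest other cluster for clusters 9 and 22, and on the midbrain and thalamic lists, which gave 0.78 and 1.47. A test of the region itself on glial genes in all nuclei was dropped, since it restated the shares.

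In 31 of 160 groups of 4 units, 1 unit lay far from the other 3 by Dixon's test at the 95% level. This count cannot be set against a chance rate of 1 in 20, since the groups share the same units and some share genes. Where the other 3 units were at 0, as for choroid plexus-like nuclei, any value above 0 was flagged. Most of the units that lay far from the others carry number 0. Hippocampus unit 0 held 2374 nuclei, against 1055 to 1167 in the others, with 43.345% of its nuclei in unnamed clusters (others 19.81% to 20.433%) and 1.011% choroid plexus-like nuclei (others 0). Cortex unit 0 had a median of 2505 UMIs (others 1106.5 to 1306) and 1606 genes (others 794.5 to 905). Its nuclei were 64.526% excitatory neuron-like (others 74.402% to 75.215%), 1.241% oligodendrocyte-like (others 0 to 0.063%) and 3.066% microglia-like (others 1.378% to 1.599%).

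In all nuclei Zbtb20 had 1448.3 CPM in hippocampus unit 0 (others 2324.6 to 2498.2) and 332.5 CPM in cortex unit 0 (others 214.2 to 226.5). Hippocampus unit 0 was far above the other hippocampal units for Abi3bp (15.1 CPM), Adam33 (31.5), Col6a1 (56.3) and Stx1a (141.5). Cortex unit 0 was far from the other cortical units for Hkdc1 (56.6 CPM) and Egr4 (24.6 CPM, others 64.2 to 68.6), and hippocampus unit 3 for Egr4 (23.0 CPM). In excitatory neuron-like nuclei, hippocampus unit 0 was far above the others for Abi3bp (25.7 CPM), Herc6 (38.9), Cux2 (93.6), Coch (25.1), Dpp10 (74.1), Rorb (47.7), Enpp2 (148.8) and Hrh3 (38.3). Cortex held 1 UMI of C1ql2, in unit 1 (0.6 CPM), and 1 of Dsp, in unit 0 (0.4 CPM), with 0 in its other units. Single units were also far from the rest for Golm1 in inhibitory neuron-like nuclei of hippocampus unit 2 (131.3 CPM), Hsd11b1 in astrocyte-like nuclei of hippocampus unit 0 (243.1 CPM, others 374.0 to 394.2) and H3f3a in endothelial-like nuclei of cortex unit 1 (122.6 CPM).

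The regional effect differed between inhibitory and excitatory neuron-like nuclei by the interaction test for 333 genes. Of those named, Col26a1 (2.93), Gpc6 (2.45) and Maf (2.32) had a higher log2 fold change, hippocampus minus cortex, in inhibitory nuclei, and Prox1 (-4.69), Slc26a10 (-4.58) and Dock11 (-4.15) a lower one. These are signed differences, and Maf had -1.58 in excitatory and 0.91 in inhibitory nuclei. Col26a1, Gpc6, Prox1, Slc26a10 and Dock11 were not tested in inhibitory nuclei alone. Most excitatory nuclei were of different subtypes in each region, which this test cannot tell from regulation within a kind of neuron.

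Only 1 of the 35 splits of the 8 units into 4 and 4, the real one, gave as many genes for all, inhibitory, astrocyte-like and endothelial-like nuclei and for the interaction. That share, the smallest the 35 splits can give, counts against chance only if the title numbers are disregarded and the 8 units are independent. The labels do not settle this. In endothelial-like nuclei each of the numbers 1 to 3 correlated best with its own number, so the condition is in doubt there. Technical steps shared within a region cannot be excluded. In excitatory neuron-like nuclei the numbers formally pair the units, and the 8 splits that part every number are too few for a share under 0.05, with 1829 genes in the real split and 0 as the highest other. The interaction uses these units too. The real count and the highest other of the 35 were 2278 and 0 for all nuclei, 10 and 2 for inhibitory neuron-like, 88 and 2 for astrocyte-like and 95 and 19 for endothelial-like nuclei, and 333 and 10 for the interaction. Beside the 0 values, the real split had 3882 genes in all and 3148 in excitatory nuclei at an unadjusted p under 0.05 in edgeR, and DESeq2 gave 2194 and 1653. The split with 19 genes grouped hippocampus unit 0 with cortex units 0, 2 and 3.

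The first pattern weighed was the larger share of glia in hippocampus. For astrocyte-like nuclei the UMI floor kept 94.3% of the difference (82.2% to 102.5% without 1 unit), and counting mixed clusters 14 and 16 as glia kept 61.5% (56.0% to 68.7%), which argues against either as the whole cause. For oligodendrocyte-like nuclei the mixed clusters gave 130.5% (122.0% to 142.0%), while the UMI floor kept 57.8% (37.1% to 73.1%) and stays open. These tests were first worded for both kinds of glia together, and the bound without 1 unit was added after the values were seen. Under the first wording the UMI floor would have been excluded for both. The region itself, with more glia in its tissue, stays open and was not tested, since the astrocyte and myelin genes in all nuclei come from the same nuclei as the shares.

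The second pattern was the unnamed clusters 9 and 22, with 436 and 171 nuclei of hippocampus, 12 and 0 of cortex, and doublet calls of 6.92% and 16.96% (45.56% and 43.73% in the mixed clusters 14 and 16). Over all genes of at least 20 CPM, 27 in cluster 9 and 78 in cluster 22 were over 1.5 times higher than in every other cluster, beyond the 95% error across nuclei, against 0 in each of the mixed clusters 14 and 16, which argues against doublets of nuclei of other clusters as the whole source. Neurons from outside the telencephalon, taken along with the hippocampus, are a candidate source, since the thalamic list summed to 2366.9 CPM in cluster 22 (at most 347.6 in named neurons) and the midbrain list to 204.3 CPM in cluster 9 (at most 18.1). The telencephalic list was 0.504 times its lowest named neuron level in cluster 9 and 0.697 times in cluster 22, where under 0.5 was needed in both, so this source stays open. Prkcd reached 1597.6 CPM in cluster 22 and Tfap2b 104.8 CPM in cluster 9, with Slc17a7, a telencephalic excitatory gene, at 62.9 CPM in 9 and 114.1 CPM in 22.

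The third pattern was the higher Agt, Hsd11b1 and Sparc in hippocampal astrocyte-like nuclei, of which the doubled cluster resolution set apart a cluster led by Agt with 134 nuclei of hippocampus and 2 of cortex. Neuronal RNA diluting the cortical nuclei would lower all astrocyte genes alike, and edgeR's test against the highest log2 fold among the transport genes, 1.15, had p-values of 2.68e-06 for Agt and 0.000152 for Hsd11b1 with Bonferroni adjustment over the 2386 genes these were picked from, which argues against dilution as their whole source, and of 0.0709 for Sparc, for which dilution stays open. That test replaced one that took no account of this choice and counted against dilution for all 3, and a first one, removal of doublet calls, which kept 124.7%, 93.1% and 83.7% of the 3 folds but does not remove free RNA. Astrocytes from outside the telencephalon could add Agt, and the telencephalic astrocyte list in nuclei with an Agt UMI was 0.507, 0.763, 0.83 and 0.815 times that in nuclei without. Those ratios exceeded the bound of 2 in 3 in 3 of 4 units, which the wording set beforehand counts against that source, but their counting intervals (0.543 to 1.058, 0.524 to 1.273 and 0.5 to 1.284) include that bound, a requirement added after the ratios were seen, so the source and the region itself cannot be told apart.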

How the results depend on the processing

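The alternatives with numbers 1 to 3 alone, number 0 alone, number 0 as a term, a UMI floor, mixed clusters counted as glia, and unnamed clusters or doublets removed from all nuclei were chosen after seeing the data.

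Counts of genes depended on the number 0 libraries and, in the smaller classes, on other choices too. Against 2278 in all nuclei, number 0 as a term gave 3665 and numbers 1 to 3 gave 4128. Against 1829 in excitatory neuron-like nuclei these gave 3102 and 3586, and number 0 alone 1158. Against 10 in inhibitory neuron-like nuclei they gave 82 and 123, number 0 alone 0, the replicate block 64, no filter 50 and doublet removal 6. Against 88 in astrocyte-like nuclei the term gave 134, numbers 1 to 3 282 and number 0 alone 32. Against 95 in endothelial-like nuclei the block gave 162, the term 211, DESeq2 52, no filter 211, doublet removal 3 and number 0 alone 188. Number 0 alone has 2 libraries of 1 unit per region. The cause was not tested for any of these. The other alternatives for genes, apart from those without 1 unit, stayed within 1.5 times the count in all units.

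Without 1 unit, counts ran from 1570 to 3094 in all nuclei, from 1136 (without hippocampus unit 1) to 2626 (without hippocampus unit 0) in excitatory, from 1 (without hippocampus unit 3) to 76 (without hippocampus unit 0) in inhibitory, from 47 (without hippocampus unit 1) to 183 (without cortex unit 0) in astrocyte-like and from 10 (without hippocampus unit 3) to 168 (without hippocampus unit 0) in endothelial-like nuclei. The interaction ran from 195 (without hippocampus unit 3) to 433 (without hippocampus unit 0).

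Gene lists past camera fell with an estimated correlation, from 9 to 4 in all, 8 to 2 in excitatory, 5 to 1 in inhibitory, 6 to 1 in astrocyte-like and 8 to 0 in endothelial-like nuclei. The cause was not tested.

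Shares of classes passing rose from 0 to 6 with the cluster resolution halved, to 5 with each library its own unit and to 5 with limma on logit shares with a replicate block. The halved setting merges clusters that mix neurons and glia, and was the first one tried. It also left unnamed a cluster of 915 nuclei led by Tac1, Syt2 and Sst. That cluster scored 0.778 for inhibitory neuron and 0.638 for the next class, striatal medium spiny neuron. With the halved setting the inhibitory difference moved from -6.62 to -2.0 points and the meningeal fibroblast difference from -0.72 to -4.3. The other 2 settings are not bound by the smallest p that 4 against 4 units can give. Libraries as units allow more assignments, and limma does not permute. Whether that alone accounts for their counts was not tested. Each library as its own unit treats 0a and 0b as separate and also gave a median UMI difference of -724.3 (exact permutation p 0.0317). Without 1 unit that difference ran from -625.5 to -159.4. The endothelial-like share difference of -0.159 points turned positive with at least 400 genes (0.41), with the UMI floor (0.65) and with numbers 1 to 3 (0.53), and ran from -0.49 to 0.57 without 1 unit. The microglia-like difference turned to 0.11 with numbers 1 to 3 and ran from -0.36 to 0.20 without 1 unit. Neither share had passed the test.

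Of the genes named, calls kept their direction and side of the threshold in 1626 of 1652 cases in all nuclei, 1609 of 1673 in excitatory, 100 of 146 in inhibitory, 416 of 470 in astrocyte-like and 378 of 481 in endothelial-like nuclei, and in 52 of 60 for the interaction. Cases in which a gene was absent from the fit are not counted in these totals. In endothelial-like nuclei the free RNA alternative kept 20 of the 26 called genes, and the rest were not tested there. With doublets removed 19 of the endothelial calls were lost. The uncalled Uty turned to -0.01 with unnamed clusters removed, and Eif2s3y to 0.07 with number 0 alone and from -0.34 to 0.11 without 1 unit. The median log2 fold change of all genes lay within 0.009 of 0 under both scalings. The self-test did not vary depth, and at the depth here it found 41% of genes changed by 1 on the log2 scale and 95% of those changed by 2 in inhibitory nuclei, and 52% and 93% in astrocyte-like nuclei. The classes not compared by gene and the comparison of astrocyte with oligodendrocyte effects have no alternatives and were not run.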

Other observations

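The lists of thalamic, midbrain and telencephalic genes used here were chosen after the clusters were seen. The telencephalic neuron and astrocyte lists share genes such as Lhx2, the midbrain list shares Otx1 with the astrocyte list, and Mef2c is also in the neocortical list.

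The unnamed cluster 9 held 1.685% of the nuclei of hippocampus unit 0 and 11.659% to 12.429% of those of hippocampus units 1 to 3. The unnamed cluster 22 held 5.476% of hippocampus unit 0 and 0.943% to 1.422% of the others.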
